A study of Mus musculus with 18 samples.

How the data were processed

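The labels give 18 libraries from testes of adult WT and Nsun7 knockout mice, in 3 RNA fractions with 3 libraries per genotype and fraction. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was captured on oligo-dT beads, large and small RNA were separated on columns, and the RNA was converted with an ultrafast bisulfite reagent. A stranded mRNA kit was used for mRNA, and a small RNA kit for small RNA and for fragmented large RNA. Per the submitters' processing notes, cutadapt, Trimmomatic, HISAT2, Bowtie2 and SAMtools were used and the build was GRCm39, with roles and versions not given in the sources used here. The labels do not say that the libraries of a group came from different animals, so p-values measure only the spread between these libraries, which may be technical. How the authors chose the listed sites is not given in the sources used here.

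Per the file headers, each table gives for every library the coverage, the count of reads showing C and the m5C level. Coverage and C counts are deposited counts of reads without normalization. The deposited level is a fraction that equals the C count over coverage to within 0.005, rounding by the authors to 2 decimals. Levels were recomputed here from the counts as percentages, so 1 blank mRNA level was read from its counts in site tests and left out of the mean. No per-sample column was left unmapped (0). Coordinates are those of the files. The gene table used for names is of GRCm38.p6, another build, so none of its coordinates were used. It matched 228 of 235 mRNA gene symbols.

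Every listed mRNA site had at least 4 unconverted reads in every WT library, while 31 sites had a knockout library with fewer. If the sites were chosen on WT reads, which is not known, sites methylated only in the knockout would not appear in the mRNA table. All 192 small RNA sites carry a plus sign for strand. Median coverage per library was 101 to 149 reads for mRNA, 134 to 183.5 for small RNA and 2395 or more at the 28S rRNA sites. Intervals on single libraries are exact binomial (Clopper-Pearson) at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

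Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named sites were fixed. Because the files give counts, the main test per site was a quasi-binomial logistic model of C reads with the site's own dispersion, using libraries with coverage of at least 10, at least 2 per group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Means over sites, classes, families, lists and rRNA sites were compared by a two-sided exact permutation test over the 10 splits of 6 libraries, whose smallest p is 0.1. The range of the 9 knockout minus WT differences is an exact 90% interval. The named sites are every site past the threshold, the 5 highest and 5 lowest differences among sites whose libraries do not overlap, the 5 highest WT levels, up to 4 sites of each gene list, the highest site per tRNA family in the enzyme classes and all rRNA sites.

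The residual degrees of freedom of the quasi-binomial model were changed after a result had been seen. The first version counted libraries fitted at 0% or 100% and made 5 small RNA calls in the fit with replicate numbers as a block. At 4 of them, where 3 to 5 libraries stood at 0% or 100%, the dispersion was under 1e-28. The other, tRNA-Ile-AAT-1-6, had p = 0.00136 in both versions of the quasi-binomial model. Its dispersion of 0.00200 in the first version was also far below that of counting error alone. Libraries fitted at 0% or 100% were then no longer counted, and the fit without the block called 0 sites in both versions. tRNA classes by enzyme were to be set by canonical position, which the tables do not carry. After the files had been examined they were set by spacing: the first of a pair of sites 8 to 11 nucleotides apart in Asp-GTC, Gly-GCC and Val-AAC, the first Leu-CAA site with the next more than 30 away, and a last Cys-GCA or Thr site 20 to 26 downstream of another. These are candidates for the named positions. Variable loop sites were not separated and are among the other cytosolic tRNA sites, and mitochondrial tRNA-Met is given within the mitochondrial class, with its site at 3875 named after its values had been seen. Classes by the bases around mRNA sites (NSUN2 and NSUN6 types) need a genome and were not analysed here.

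Replicate numbers were checked for pairing by the correlation of same-numbered libraries' standardised residuals. These were 0.0904, -0.0132 and 0.0798 in mRNA, whose m5C was not taken as paired. The coverage of same-numbered mRNA libraries correlated at 0.557, 0.686 and 0.817, and that of differently numbered ones at -0.749 to 0.502, so mRNA coverage was taken as paired by the limit of 0.1 per pair, and its edgeR fit called 0 sites with and without the block (28 and 5 at an unadjusted p under 0.05). In small RNA the residuals correlated at 0.309, 0.607 and 0.494, all above 0.1, and at -0.493 to 0.321 for different numbers (knockout replicate 1 correlated best with WT replicate 3), while the unweighted levels gave -0.165, 0.0303 and -0.274. The weighted measure was used, so small RNA m5C was taken as paired, and the fit with the block also called 0 small RNA sites. Measures differ on whether the numbers pair the libraries of either fraction, so fits with and without the block are both given. Large RNA, with 3 sites, was not checked.

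Tests were tried on simulated data with the real coverage and levels and 20 changed sites per size, over 10 draws. All simulated sites of a fraction shared the same beta-binomial spread between libraries, taken from the deep sites (correlation 0.000161 in mRNA and 0.000456 in small RNA). A shared spread favours the moderated version, so its shares may overstate what it recovers in real data. The spread is a median over the deep sites, so sites that vary more were not simulated. The shares of every version may therefore be too high. For mRNA the quasi-binomial model recovered 35%, 20% and 4% of sites with a knockout level of 10%, 50% and 75% of WT, and a version with dispersions moderated over sites 99%, 60.5% and 11.5%. For small RNA the shares were 98.5%, 81.5% and 67%, and 99.5%, 86% and 71%. The moderated model and limma on levels were added after the data had been seen. Coverage itself was compared with edgeR's quasi-likelihood test on TMM-scaled counts, also added later, which recovered 64% of simulated 2-fold changes in mRNA coverage (251 sites) and 90.5% in small RNA (192 sites). Alternatives covered the scale, minimum level, coverage, block, summary over sites and each library left out. R 4.3.3 with limma 3.58.1 and edgeR 4.0.16 was used.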

Results

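RNA 5-methylcytosine (m5C) was measured in testes of adult wild-type (WT) mice and of adult mice lacking Nsun7, a testis-expressed member of the NOL1/NOP2/Sun family to which most RNA m5C methyltransferases belong. Ultrafast bisulfite sequencing converts unmethylated cytosine to uracil. The share of reads still showing C at a position is taken as its m5C level. Unmethylated cytosines left unconverted would count as m5C too, and the completeness of conversion was not measured here. Polyadenylated mRNA, large RNA and small RNA were each sequenced in 3 WT and 3 knockout libraries, 18 libraries in all. The tables list 251 mRNA sites in 235 genes, 192 small RNA sites in 128 RNAs and 3 large RNA sites. Coverage summed over the listed sites was 42086 to 55140 per mRNA library and 4674265 to 5096438 per small RNA library. For large RNA libraries it was 5472 to 9070. These sums count a read once at each listed site it covers, so they can exceed the number of separate reads. The series title describes NSUN7 as catalytically inactive on RNA and as a regulator of sperm flagellum assembly, and the comparison of genotypes asks whether any listed site depends on Nsun7. No listed mRNA site lies in Nsun7, so these tables hold no check of the knockout itself.

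In mRNA, levels were low at most sites and alike in both genotypes. The median site stood at 10.1% in WT and 11.1% in the knockout, and 12 sites had at least 50% in WT. Bag6, which encodes a chaperone needed in spermatogenesis, had the highest level, 91.1% ± 0.419 in WT and 92.2% ± 0.0988 in the knockout (SD, n = 3, coverage 128 to 417). Myl4, a myosin light chain gene, stood at 64.3% ± 4.14 and 59.7% ± 8.26, and D1Pas1, a testis DEAD-box helicase gene, at 62.3% ± 1.79 and 61.2% ± 5.35 (SD, n = 3). Prox2 had 63.0% and 56.5%, and the non-coding Gm16835 had 62.2% and 60.6%, both at coverage of 29 reads or fewer. The Prox2 libraries ranged from 53.8% to 71.4% in WT and from 45.8% to 66.7% in the knockout.

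Among the 251 mRNA sites, the quasi-binomial model with Benjamini-Hochberg adjustment called 0 sites different between genotypes. At an unadjusted p under 0.05 there were 20 sites, 11 lower and 9 higher in the knockout, where 12.55 come by chance. limma on the levels called 0 sites as well, with 14 at an unadjusted p under 0.05. The 3 knockout values lay wholly on one side of the 3 WT values at 29 sites, 11.6% of all, 16 lower and 13 higher in the knockout, where chance gives 10%. The knockout level was lower at 150 sites and higher at 101.

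The mRNA sites with the most negative differences among those whose libraries lay apart were in Tpgs2, Egln2, 4932414N04Rik, Cfap52 and Asxl1. Tpgs2, a subunit of the tubulin polyglutamylase complex, stood at 55.8% ± 6.31 in WT and 38.5% ± 4.54 in the knockout (SD, n = 3; chromosome 18, position 25301899; coverage 11 to 42). Egln2, an oxygen-sensing prolyl hydroxylase gene, had 25.2% and 16.9%, and 4932414N04Rik had 30.6% and 23.5%. Asxl1, a Polycomb-associated gene, had 11.7% ± 0.121 and 5.99% ± 1.79 (SD, n = 3; chromosome 2, position 153238687). At the other end, A730035I17Rik stood at 24.3% ± 3.71 in WT and 39.8% ± 6.28 in the knockout (SD, n = 3; chromosome 5, position 98333589; coverage 17 to 50). The fructose transporter gene Slc2a5 had 8.21% and 15.3%, Tln2 (talin 2) 15.8% and 20.7%, Rbm28 8.11% and 12.0%, and Sord (sorbitol dehydrogenase) 10.1% and 13.3%. The difference moved by over 1.5 times with 1 library left out at Egln2 (-8.33 points, -5.13 without WT replicate 3), Slc2a5 (7.10 points, 4.50 without knockout replicate 2) and Sord (3.25 points, 1.92 without knockout replicate 2). None of these 10 sites passed the quasi-binomial model, whose adjusted p was 0.340 at best. Without knockout replicate 3, Asxl1 alone passed, at an adjusted p of 0.0284 in the quasi-binomial model. That model uses the site's own dispersion. The WT libraries there stood at 11.7%, 11.7% and 11.9% at coverage of 94 to 127, closer together than counting reads alone would give. With all 6 libraries the adjusted p at Asxl1 was 0.740 in the moderated model and 0.789 in Fisher's test on pooled reads.

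**Figure D1:**
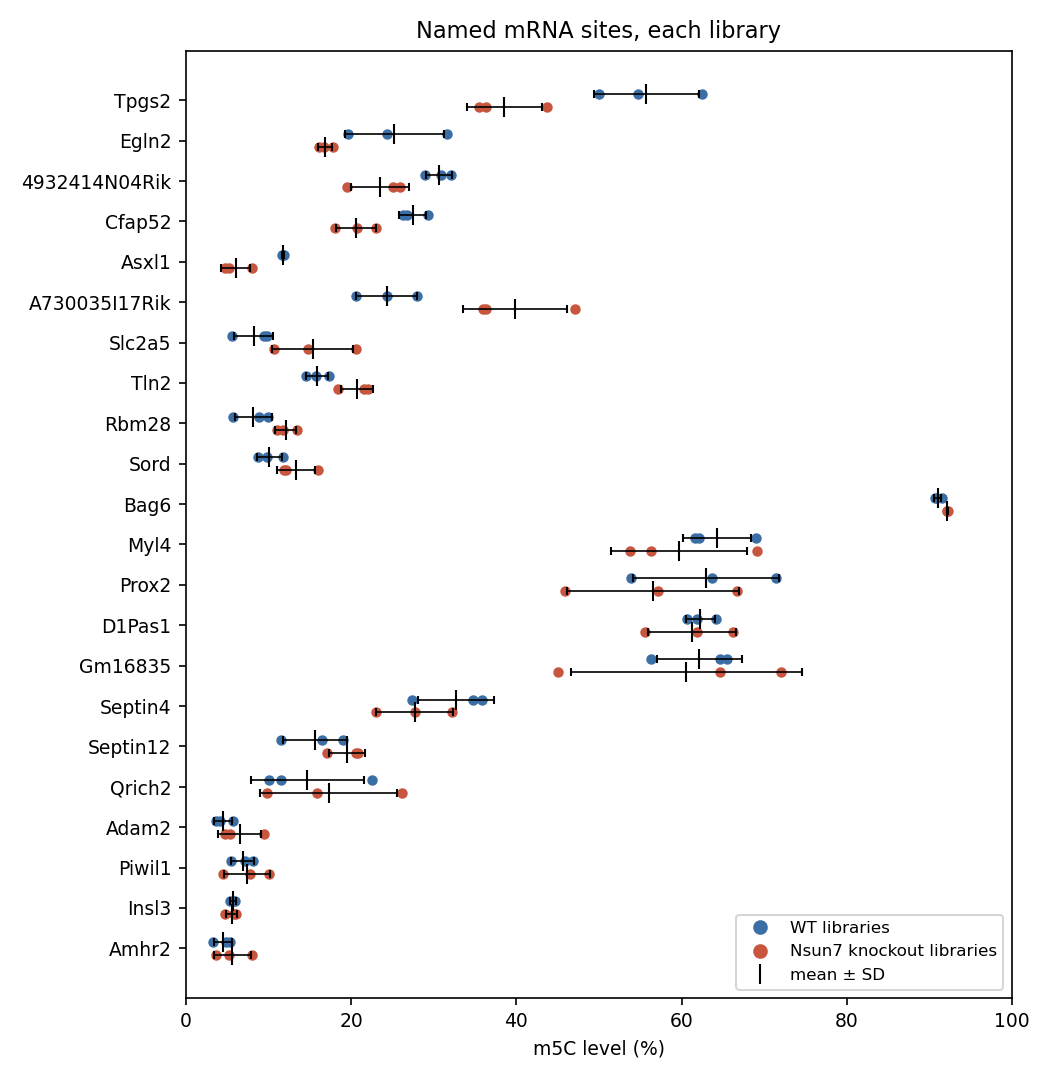
m5C level in percent at each named mRNA site, one point per library (3 WT, 3 Nsun7 knockout), with the mean and SD of each group. Bag6 lies at 91.1% in WT and 92.2% in the knockout, and the WT and knockout points of Tpgs2 and A730035I17Rik do not overlap.

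Of the sperm flagellum genes fixed beforehand, 6 had a listed site, in Cfap43, Cfap52, Drc3, Qrich2, Septin4 and Septin12. Their mean level was 19.3% ± 2.06 in WT and 18.7% ± 1.69 in the knockout (SD, n = 3), a difference of -0.590 percentage points with a range of -4.14 to 3.01 over the 9 pairs of libraries. Cfap52, a protein of the axonemal doublet microtubules, had 27.4% ± 1.66 and 20.6% ± 2.47, with its libraries apart. Septin4 and Septin12, which form the ring between the midpiece and principal piece of the sperm tail, had 32.7% and 27.7% (Septin4) and 15.6% and 19.5% (Septin12), with exact permutation p of 0.3 and 0.2. With 1 library left out the Septin4 difference of -5.00 points ranged from -7.64 (without WT replicate 1) to -2.66 (without knockout replicate 1), and that of Septin12, 3.85 points, from 1.74 (without WT replicate 3) to 5.51 (without WT replicate 1). Qrich2 had 14.6% ± 6.84 and 17.3% ± 8.28 at coverage of 19 to 61 reads. The exact permutation test gave p = 0.6 for the list, where 3 against 3 libraries cannot go below 0.1. The direction turned when the median over sites was taken, to 3.03 points, and without WT replicate 3 (0.560) or knockout replicate 1 (0.0319). Within same-numbered pairs of libraries the list was lower in the knockout in all 3, at differences of -0.158, -0.649 and -0.964 points (exact sign-flip p = 0.25, the smallest 3 pairs can give).

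The other gene lists had sites in fewer than 3 genes, the minimum set beforehand for testing a list, and exact permutation tests of their 4 sites gave p of 0.3 to 0.9. Adam2, a sperm surface protein gene on the acrosome list, had 4.48% in WT and 6.51% in the knockout. Its knockout libraries stood at 4.67%, 9.48% and 5.37%, so replicate 2 carried much of the difference. Piwil1, which encodes a piRNA-binding protein, had 6.88% and 7.41%. The Leydig cell gene Insl3 stood at 5.65% ± 0.364 and 5.51% ± 0.653 (SD, n = 3) at coverage of 1122 to 2795 reads, and Amhr2, the receptor for anti-Müllerian hormone, at 4.43% and 5.60%. No site was listed in the spermatid chromatin genes, the RNA m5C enzymes and binders or the ribosomal protein genes. Averaged over the 250 mRNA sites with a level in all 6 libraries, m5C was 16.9% ± 0.134 in WT and 16.7% ± 0.324 in the knockout (SD, n = 3), a difference of -0.270 points with a range of -0.743 to 0.117 over the pairs of libraries. The exact permutation test gave p = 0.3, and the median over sites turned the direction, to 0.0299 points. The same-numbered pairs differed by -0.241, -0.0802 and -0.488 points (exact sign-flip p = 0.25), and without knockout replicate 3 the difference was -0.0855.

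**Figure D2:**
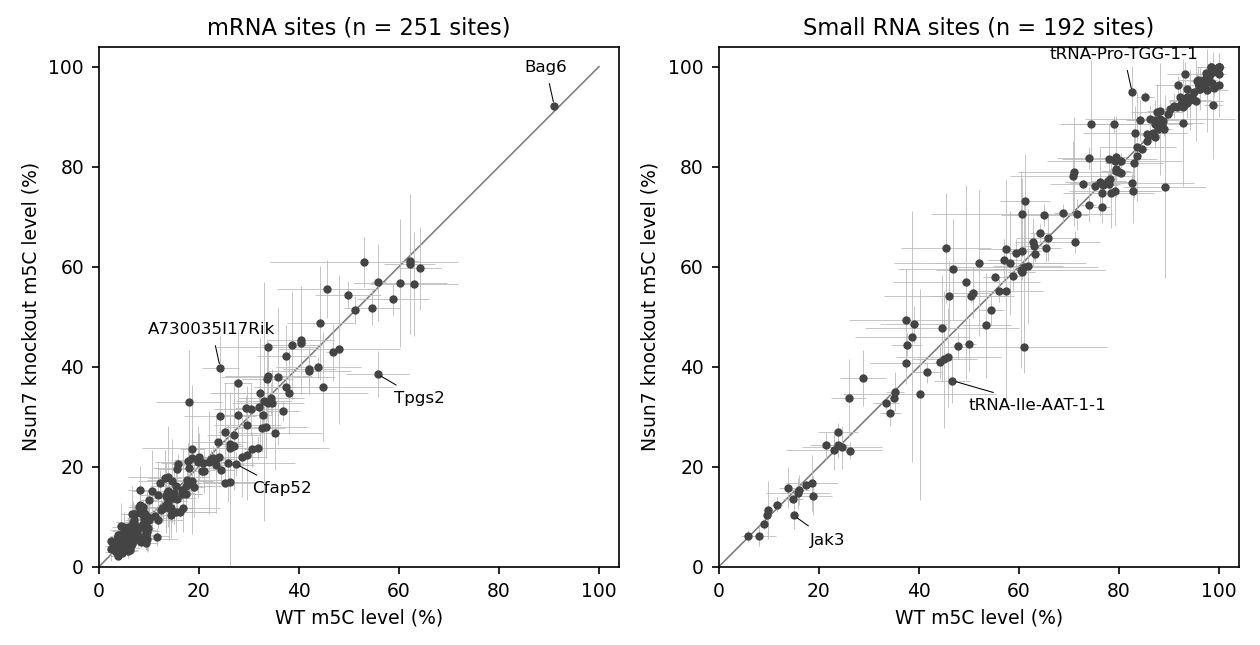
Mean m5C level of each site in the Nsun7 knockout against WT, in percent, with the SD of 3 libraries on both axes, for the 251 mRNA sites (left) and the 192 small RNA sites (right). Points lie along the line of equal levels, and the labelled RNAs are among those named in the text.

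How large a loss these mRNA data could hide depends on the site. The 95% limma interval excluded a complete loss of m5C at 240 of the 251 sites and a loss of 50% of the WT level at 117. limma draws each site's variance towards one shared by all sites, so intervals can stay wide at deep sites of low level. At Insl3 the interval ran from -2.70 to 2.42 points, with SDs of 0.364 in WT and 0.653 in the knockout. Both counts thus depend partly on the WT level. The lowest observed ratio of knockout to WT mean was 0.508, at Eif4b. On simulated data with a known loss to 10% of the WT level, the quasi-binomial model recovered 35% of changed mRNA sites and its version with dispersions moderated over sites 99%. False calls made up 5.6% and 3.66% of the calls. All simulated sites shared the same spread between libraries, which favours moderation, so the 99% may be too high for these data. The 35% may be too high as well, since sites that vary more than the shared spread were not simulated. In the real data the moderated model also called 0 mRNA sites.

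Small RNA sites were far more highly methylated, with a median of 79.4% in WT and 80.1% in the knockout, and 64 of 192 sites at or above 90% in WT. Cytosolic tRNAs held 139 of the sites in 83 tRNA genes, mitochondrial tRNAs 8, tRNA-like tRX genes 6 and other RNAs 39. The upstream site of tRNA-Asp-GTC-1-5, at a spacing that fits the anticodon loop position methylated by DNMT2, had 97.8% ± 0.0511 in WT and 97.8% ± 0.108 in the knockout (SD, n = 3, coverage 18857 to 55565). The upstream site of tRNA-Gly-GCC-2-8 stood at 86.2% ± 2.05 and 86.3% ± 0.374. The upstream site of tRNA-Val-AAC-2-1 (chromosome 13, position 23469608) had the highest ratio of knockout to WT among small RNA sites, 1.40, with 45.4% ± 8.97 and 63.7% ± 11.0 (SD, n = 3) at coverage of only 8 to 26 reads and an exact permutation p of 0.2. The upstream site of tRNA-Leu-CAA-2-1, a candidate for the NSUN2 wobble position, had 77.9% ± 3.47 and 77.1% ± 1.54. The downstream sites of tRNA-Thr-TGT-3-1 and tRNA-Cys-GCA-3-1, candidates for the NSUN6 acceptor position, stood at 97.1% and 96.4% in WT and at 96.9% and 97.2% in the knockout. Mitochondrial tRNA-Met, the substrate of NSUN3, had 2 listed sites. The upstream one, position 3875 of the mitochondrial genome and a candidate for the wobble position, stood at 55.2% ± 2.25 and 57.9% ± 0.448 (SD, n = 3, coverage 263 to 384), with its libraries apart by 0.105 points at the nearest and an adjusted p of 0.867 in the quasi-binomial model. The downstream one, position 3888, had 90.2% ± 1.49 and 91.6% ± 1.83.

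The quasi-binomial model tested 184 small RNA sites and called 0, with 7 at an unadjusted p under 0.05 where 9.2 come by chance. limma on the levels called 0 of 187, also with 7 at an unadjusted p under 0.05. The libraries of the 2 genotypes did not overlap at 22 sites, 11.5% of all, 11 in each direction, where chance gives 10%. The 95% limma interval excluded a loss of 50% of the WT level at 170 of 187 small RNA sites and a complete loss at all 187.

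Among sites whose libraries lay apart, tRNA-Ile-AAT-1-1 had 46.7% ± 3.63 in WT and 37.2% ± 4.43 in the knockout (SD, n = 3, coverage 31 to 62). The sites of tRNA-Gly-GCC-4-1 at position 111789229 (50.1% and 44.5%), tRNA-Val-CAC-2-1 at 170939059 (76.6% and 71.9%), tRNA-Thr-CGT-1-1 at 13255257 (44.3% and 41.0%) and Jak3 (15.0% and 10.3%) followed. On the higher side, both neighbouring sites of tRNA-Pro-TGG-1-1 stood at 82.7% and 85.3% in WT and at 94.8% and 94.0% in the knockout, at coverage of 21 to 46 reads. tRNA-Val-CAC-2-3 at 48709417 had 39.0% and 48.5%, tRX-Lys-NNN-16-1 74.0% and 81.7%, and Lrig1 37.6% and 44.4%. Of these 10 sites, 5 moved by over 1.5 times with 1 library left out. Without knockout replicate 2, tRNA-Gly-GCC-4-1 moved from -5.60 to -2.60 points and tRNA-Val-CAC-2-1 from -4.61 to -2.9996, and without knockout replicate 3 tRNA-Thr-CGT-1-1 from -3.27 to -1.29. tRNA-Val-CAC-2-3 moved from 9.50 to 5.63 points without WT replicate 2, and tRX-Lys-NNN-16-1 from 7.70 to 4.02 without WT replicate 1. The lowest adjusted p in the quasi-binomial model was 0.309, at position 98464670 in tRNA-Pro-TGG-1-1. The highest WT levels were 100% in Tle4, Frmd5, Arl15, Piwil1 and Gm16741, each at coverage of 30 reads or fewer.

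**Figure D3:**
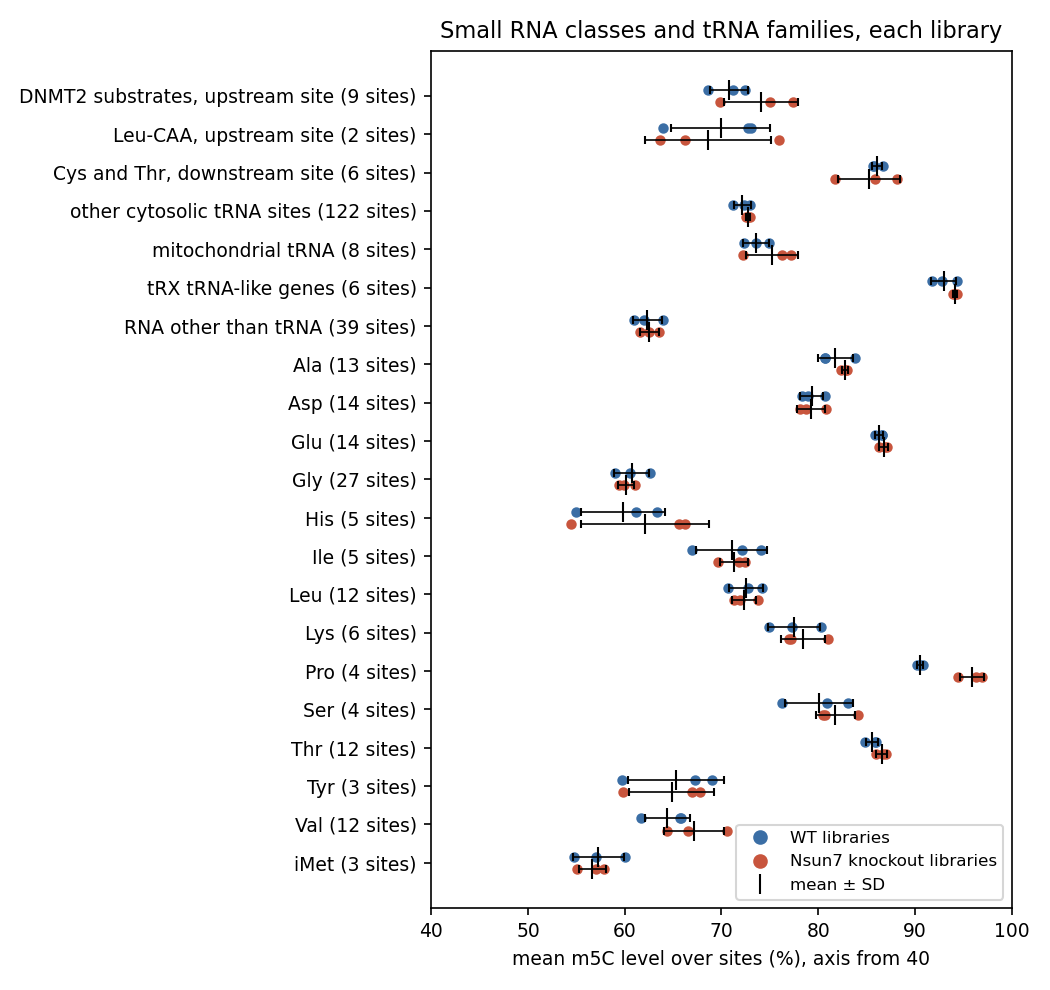
Mean m5C level in percent over the sites of each small RNA class and each tRNA amino acid family, one point per library (3 WT, 3 Nsun7 knockout), with the mean and SD of each group. The horizontal axis starts at 40%. WT and knockout points are apart for Pro and Thr tRNAs, by 3.63 and by only 0.00945 points at the nearest.

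By class, the upstream sites of tRNA-Asp-GTC, Gly-GCC and Val-AAC averaged 70.7% ± 1.97 in WT and 74.1% ± 3.85 in the knockout over 9 sites (SD, n = 3), with the knockout higher in all 3 same-numbered pairs, by 3.81, 1.28 and 4.97 points (exact sign-flip p = 0.25, the smallest 3 pairs can give). The shallow tRNA-Val-AAC-2-1 site carried much of this: without it the difference of 3.35 points was 1.49 (p = 0.5 in the exact permutation test), and over the 7 sites with at least 10 reads in all libraries it was 0.571. That site was left out for having the highest ratio of knockout to WT in the class, so a fall in the difference follows from the choice. The Leu-CAA upstream sites averaged 69.9% and 68.6% (2 sites), the downstream Cys and Thr sites 86.0% and 85.2% (6 sites), mitochondrial tRNA 73.6% and 75.2% (8 sites) and tRX genes 93.0% and 94.1% (6 sites). The other cytosolic tRNA sites averaged 72.2% ± 0.895 and 72.7% ± 0.213 (122 sites), and RNAs other than tRNA 62.3% and 62.5%. The exact permutation test, which does not use the pairs, gave p of 0.3 or more for each class, and 0.875 or more after Benjamini-Hochberg adjustment over the 7 classes. Leaving out 1 library moved the difference by over 1.5 times or turned it in each of the 7 classes, for the DNMT2 candidates to 1.69 without knockout replicate 3 and 5.46 without knockout replicate 2. Of 14 amino acid families, the libraries of Pro (90.5% ± 0.332 and 95.9% ± 1.26, 4 sites) and Thr (85.5% ± 0.595 and 86.5% ± 0.519, 12 sites) did not overlap, each with p = 0.1 in the exact permutation test and 0.7 after adjustment. The nearest libraries lay 3.63 points apart for Pro and 0.00945 for Thr. In each of these 2 families, 1 tRNA gene was left out, chosen as the gene whose removal shrank the difference most. A smaller difference was thus fixed by the choice, and the gene chosen was a shallow one in both. Without tRNA-Pro-TGG-1-1 the Pro difference of 5.38 points was 0.303 (p = 0.4 in the exact permutation test), over the deep sites of tRNA-Pro-CGG-1-3 (1457 to 2005 reads), and without tRNA-Thr-CGT-3-1 (3 to 16 reads) the Thr difference of 0.993 points was -0.210. In same-numbered pairs of libraries 4 of the 14 families were higher in the knockout in all 3 pairs, Pro, Thr, Glu (0.426, 0.498 and 0.369 points, 14 sites) and Val (0.719, 2.68 and 4.82 points, 12 sites), each with an exact sign-flip p of 0.25. By chance a share of 0.25 of families would agree in direction in all 3 pairs. The Val family includes the shallow tRNA-Val-AAC-2-1 site. Over all 192 small RNA sites the mean was 71.2% ± 0.802 in WT and 71.8% ± 0.0869 in the knockout, with p = 0.4 in the exact permutation test, and the median over sites turned the direction, to -0.0987 points. The difference of 0.626 points was 0.229 without WT replicate 1 and 1.03 without WT replicate 2.

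In large RNA, 2 sites of 28S rRNA were nearly fully methylated in both genotypes. Position 3438, the site set by NSUN5 in the cytosolic ribosome, had 93.4% ± 1.53 in WT and 92.8% ± 0.669 in the knockout (SD, n = 3, coverage 2952 to 4748). Position 4099, the site of NSUN1 (NOP2), had 94.6% ± 0.499 and 93.7% ± 0.428 (SD, n = 3, coverage 2395 to 4175). Position 842 of mitochondrial 12S rRNA, the site of NSUN4, had 87.1% ± 4.46 and 90.2% ± 1.55 (SD, n = 3) at coverage of only 77 to 147 reads. The differences were -0.580, -0.941 and 3.12 points, with ranges over the pairs of libraries of -2.77 to 1.57, -1.73 to 0.0493 and -3.41 to 7.50. Exact permutation tests gave p of 0.6, 0.2 and 0.4. Leaving out 1 library moved 2 of the 3 differences by over 1.5 times. At 3438 it was 0.139 points without WT replicate 3, -1.38 without WT replicate 2 and -0.205 without knockout replicate 3, and at 842 it was 5.69, 1.89 and 1.76 points without WT replicates 1, 2 and 3.

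**Figure D4:**
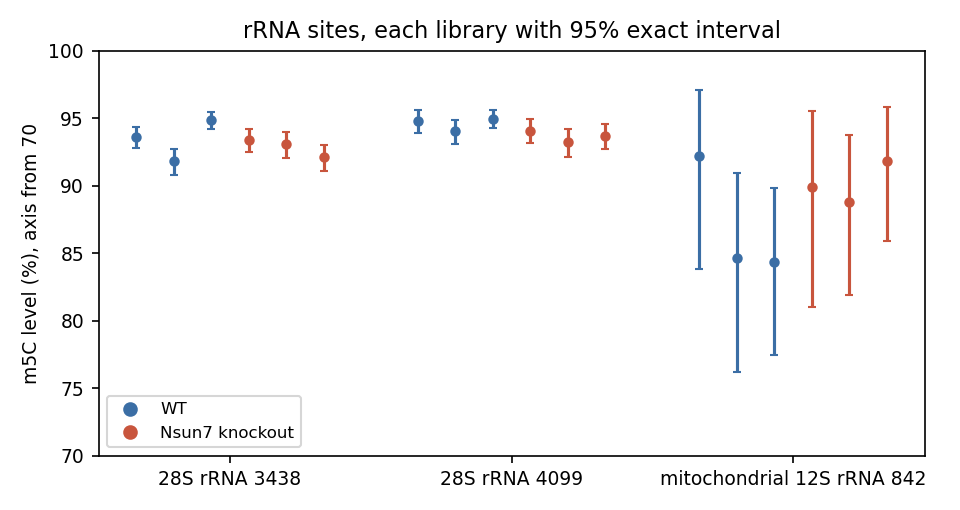
m5C level in percent at the 3 rRNA sites, one point per library with its 95% exact binomial interval, which covers counting error only. The vertical axis starts at 70%, and WT and knockout points overlap at all 3 sites.

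Against the splits that mix genotypes, the WT and knockout split gave the lowest SD over mRNA sites of the difference between groups, 3.47 points, where the 9 other splits of the 6 libraries gave 3.50 to 4.15. It also gave the most mRNA sites at an unadjusted p under 0.05 in the quasi-binomial model, 20 against 9 to 16, and 10 splits are too few for a share under 0.05. In small RNA these counts were 7 against 4 to 15. The SD for small RNA was 3.78 points, within the 3.36 to 4.60 of the other splits. At sites with at least 50 reads in every library the SDs were 2.04 and 1.80 points, and the mRNA value was no longer the lowest, with 1.75 to 2.25 over the other splits. Across sites, WT and knockout levels correlated at r = 0.973 in mRNA and 0.987 in small RNA, where sites are not independent replicates.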

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

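The coverage tests here were chosen after the data had been seen, as was the test of scaling. Coverage, which the comparisons above use only as a denominator, stood higher in the knockout at all 5 sites of Rprl2, an RNase P RNA-like gene on chromosome 3. The folds there were 2.07, 1.79, 1.87, 1.77 and 2.51, and 1 site of Gm37350 had a fold of 1.52. These folds come from the edgeR fit without the block under TMM scaling, which itself called 0 sites. The other Gm37350 site, at 5925524, had a fold of 1.32 and passed in none of the edgeR fits below (adjusted p 0.458 with the block and TMM scaling). The 5 Rprl2 sites lie on one RNA and count as a single observation. These 6 sites passed an adjusted p of 0.05 in the edgeR fits with replicate numbers as a block, under TMM scaling and under library totals without the Glu tRNA sites. The blocked fit scaled to full library totals called 0 (20 sites at an unadjusted p under 0.05). Glu tRNA sites hold 66.5 to 71.7% of small RNA coverage, so full totals rest on sites among which tRNA-Glu-TTC-1-1 has nearly equal coverage in all libraries. Without the block, edgeR called 0 sites under TMM, library totals, median ratio and totals without Glu tRNA, with 13, 9, 9 and 8 sites at an unadjusted p under 0.05 and a lowest adjusted p of 0.274. The same-numbered small RNA libraries correlated at 0.289, 0.265 and 0.0575 in coverage, not all over 0.1, while their m5C residuals all correlated above 0.1. Coverage itself thus does not show the pairing on which these calls depend, and whether the block is right for them stays open. Groups of 3 libraries are too small for a search for single outlying libraries.

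Summed Rprl2 coverage was 1.98-fold higher in the knockout after TMM scaling, with p = 0.1 in the exact permutation test, the smallest it can give, and 950.1 and 975.4 scaled reads in the nearest libraries, WT replicate 3 and knockout replicate 1. Library size or scaling would bring the fold near 1 under some scaling, and the lowest fold over 4 scalings was 1.88. The 4 scalings differ too little between genotypes to bring such a fold near 1, so this outcome was nearly fixed. The value shows only that none of these 4 scalings accounts for the fold. The TMM-scaled reads were 406, 736 and 950 in WT and 975, 2070 and 1100 in the knockout, in replicate order. Knockout replicate 2 and WT replicate 1 thus carry much of the fold. With 1 library left out, the lowest folds were 1.49, without knockout replicate 2, and 1.64, without WT replicate 1. No single library is the whole of it. Apart from both of these, WT stood at 736 and 950 scaled reads and the knockout at 975 and 1100, much closer together. These libraries are the lowest of WT and the highest of the knockout, so a smaller difference without them follows from the choice. A genotype difference in this RNA, a scaling not tried here, reads from a related RNA and the chance of having looked at many sites all stay open. In the blocked TMM fit, the real split called 6 sites and the highest of the other splits that part all 3 pairs 0, so 1 of 4 splits gave as many, too few for a share under 0.05.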

How the results depend on the processing

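Chosen after the data had been seen were limma on levels, the moderated model, Fisher's test on pooled reads, the first version of the degrees of freedom, coverage limits on means, a class without 1 site or family without 1 RNA, sums of reads, all alternatives for named sites, all coverage fits and the tests by other splits of the m5C site counts. The count of 0 sites held in mRNA and small RNA under limma on levels or logits, trend and robust settings, a minimum level, coverage of 20 or 50, complete libraries, the moderated model and the replicate block (0 and 0, also moderated). The effect size limit only picks among the main calls, so its 0 was fixed in advance. The count of 0 did not hold at an unadjusted p (20 and 7), in small RNA for Fisher's test on pooled reads (24), which has no replicate error, or for the first version of the replicate block (5, smallest adjusted p 1.23e-27). At 4 of these 5 the dispersion was under 1e-28 and the later version gives no p. The other, tRNA-Ile-AAT-1-6, had p = 0.00136 in both quasi-binomial versions, adjusted to 0.0496 and 0.243. Its dispersion was only 0.00200 in the first version, and the moderated model with the block gave an adjusted p of 0.803. With 1 library left out the count of called sites was 0 to 1 in mRNA (Asxl1, without knockout replicate 3) and 0 in small RNA. The real split gave 0 m5C sites and the highest other split 1 in mRNA and 0 in small RNA, and coverage without the block 0 and 0 in both tables. With 0 in the real split all 10 splits give as many by construction, which says nothing about chance. With the replicate block mRNA coverage gave 0 sites, and small RNA coverage 6, also with totals without Glu tRNA (6).

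Differences of means that missed the threshold changed sign, with the cause not tested. With the median over sites they were 0.0299 points (mRNA), 3.03 (flagellum list), -0.0987 (small RNA), 1.03 (Cys and Thr), -0.444 (other cytosolic tRNA), -0.391 (tRX) and -2.80 (other RNAs). On the logit scale they were 0.0697 (Cys and Thr) and -0.0659 (tRX), and with reads summed over sites -0.0373 points (small RNA). Thr tRNA was -0.210 without tRNA-Thr-CGT-3-1. With 1 library left out, ranges were -1.55 to 0.560 (flagellum list), -4.99 to 1.15 (Leu-CAA), -2.23 to 0.943 (Cys and Thr), -0.428 to 1.05 (other RNAs) and -1.38 to 0.139 (28S 3438). Families with libraries apart numbered 2, 1 with coverage of 10 in all libraries, and 4 with the replicate block, read as all 3 pairs in one direction. The SDs over sites moved to 2.04 and 1.80 points with coverage of 50, which leaves fewer shallow sites. Sign-flip tests of pairs cannot go below 0.25 and changed no other call.

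Named sites that missed the threshold changed sign, or came to 0 for Piwil1 in small RNA, with 1 library left out, with ranges in points of -3.55 to 1.78 (D1Pas1), -7.30 to 6.20 (Gm16835), -1.83 to 6.56 (Qrich2), -0.765 to 2.00 (Piwil1 in mRNA), -0.385 to 0.230 (Insl3), -0.0441 to 2.18 (Amhr2), -5.56 to 0 (Piwil1 in small RNA), -1.05 to 0.877 (tRNA-Gly-GCC-2-8), -2.70 to 0.691 (tRNA-Leu-CAA-2-1) and -0.525 to 0.114 (tRNA-Thr-TGT-3-1). Insl3 was 0.0554 points with reads summed over libraries. Classes by surrounding bases and their motif alternatives were not run, since they need a genome. Depth limits what can be seen at the 123 mRNA sites under 10% in WT, which had a median of 9.33 unconverted reads per WT library.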

Other observations

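The tests of shared positions and of the Glu tRNA coverage below were chosen after the values had been seen. Among cytosolic tRNA sites, the 49 with mean coverage of at least 1000 had a median level of 92.4%, the 38 with 100 to 1000 reads one of 72.6%, and the 52 under 100 reads one of 67.5%. Of the 39 sites on RNAs other than tRNA, 13 had at least 90% over all libraries, at a median coverage of 16.2 reads, 9 had under 20%, at 151.5 reads, and 17 lay between. All 4 sites of tRNA-Gly-GCC-4-1 were lower in the knockout, by -5.60, -2.98, -3.23 and -3.50 points, on overlapping reads. With 1 value per tRNA gene, 11 of 83 genes (13.3%) had libraries apart, 6 higher and 5 lower in the knockout, where chance gives 10%.

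One position, on chromosome 8 at 72142024, is listed in both tables, as Insl3 in mRNA and as Jak3 in small RNA. It stood at 5.65% in WT and 5.51% in the knockout in mRNA, and at 15.0% and 10.3% in small RNA. The knockout difference in small RNA minus that in mRNA was -4.55 points, with p = 0.06 in an exact permutation within each table and 0.0348 in the quasi-binomial model, so the 2 tests fall on different sides of 0.05.

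mRNA sites leaned lower in the knockout, at 150 of 251 sites. A selection of sites on WT reads would show where reads are few; the lean was 61.9% (95% exact interval 52.8 to 70.4) at sites with more unconverted reads and 57.6% (48.4 to 66.4) at the others. The intervals treat sites as independent, which libraries shared by all sites make too narrow, and other splits reached 57.1% at the sites with more reads, so this explanation stays open. A single knockout library may carry part of it: the share was 54.2% (47.8 to 60.5) without replicate 3, 56.2% without replicate 2 and 59.8% without replicate 1. The real split put 150 sites on one side and the highest other split 138, so 1 of 10 splits gave as many, too few to exclude chance.

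Coverage of the tRNA-Glu-TTC-1-1 sites was nearly equal in all 6 libraries, 961677 to 978773 reads. Its higher coefficient of variation was 0.685%, against 3.98% at the next lowest of the sites with at least 1000 reads in every library. A depth ceiling near this value in the authors' processing is a candidate explanation, and no biological one was tested. Levels at such sites would then rest on a subset of reads.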
